A study of Homo sapiens with 6 samples.

How the data were processed

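The series holds 6 arrays of HEY cells, 3 per group, and 2 groups. Per the labels' protocols, 60000 cells per well were transfected with 30 nM of a miR-200b precursor or with a negative control precursor, and RNA was taken 48 h later. Total RNA was isolated with a column kit, its integrity was read on a Bioanalyzer, and cDNA was made and amplified from the 3' end before biotin labelling, per the labels' protocols. Amplification from the 3' end makes the signal of a probe set depend on its distance from that end and on the length of the cDNA.

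The deposited values are log2 GCRMA signals, 1 per probe set and array, per the series' design text and the labels. As generally run, GCRMA corrects the background by probe sequence, normalizes arrays by quantiles and summarises each probe set, which sets dim probe sets at low values with little order among them. The submitters' processing notes name GCRMA, MAS5 and Affymetrix Expression Console, and their versions are not given in the sources used here. The design text also mentions MAS5 present or absent calls and predicted miRNA targets, which were not used here. Columns of the value table were matched to samples by name, and 0 columns were left unmatched. A search for identical arrays found 0.

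Of 54675 probe sets, 62 spike-in and other control probe sets were left out of the tests. GEO's annotation of the array gave 1 gene symbol for 41091 of the remaining 54613 probe sets, several for 1801 and none for 11721. Symbols of 41037 probe sets were updated through the gene ID with a table of RefSeq genes of assembly GRCh38.p14, used for names only, and a probe set with several symbols names no gene here. Probe sets whose mean over all 6 arrays was above the median of these means, 1.37 on the log2 scale, were tested, which left 27306 probe sets and 11842 genes. A gene is represented by its brightest tested probe set, and 6030 genes had more than 1.

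The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior, group as the only term), with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. Fold changes are miR-200b minus control, and a fold is 2 to the power of that difference. The 24 gene lists were written before the data were examined, as were the rule for named genes and most alternative settings. The lists of reported targets, epithelial and mesenchymal genes come from general knowledge of the miR-200 family and were not chosen on these samples. A list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 23 lists with at least 3 tested members. It was tested again with an estimated correlation, which called 0 lists where the preset one called 3. For the NF-kB and inflammatory cytokine list the estimated correlation was 0.0137, near the preset one. Its unadjusted camera p still went from 3.86e-05 to 0.0159. The 2 versions therefore differ in more than the correlation, and the lost calls do not rest on correlation alone. fry, which asks whether a list's genes move on balance one way without comparing them with other genes, called 9 lists, and its mixed version, for change in either direction, called 21. Single control probe sets were compared by exact permutation of 3 against 3 arrays, two-sided, whose smallest p is 0.1.

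Genes named in the text are the 14 with the largest fall and the 14 with the largest rise among the genes changed whose 3 miR-200b arrays all lie on 1 side of the 3 controls, without symbols that begin with LOC or LINC or end in -AS1. Up to 4 measured members of each list with the smallest adjusted p were added, together with ZEB1, ZEB2, CDH1, EPCAM, VIM, CDH2, FN1, ESRP1, SEC23A, QKI, CFL2, WASF3, GAPDH and ACTB in any case. Members of a list outside this rule were chosen after their values were seen. A further part of the rule, and a planned test of genes with a miR-200b seed site, need 3' UTR sequence and were not run here. No coordinates are given for the same reason.

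A fold against a group whose mean lay under 2.05, the highest value of blood and immune cell marker probe sets on any array, is given as a lower bound computed against that level. Such a bound, written as "at least", carries no sampling error, and a higher background would give a smaller fold. The steps were tested on simulated data drawn for the 27306 probe sets of this comparison. There 4 of 67 changes of 1 on the log2 scale were recovered (5.97%), 58.2% of 67 changes of 2 and 89.4% of 66 changes of 4, with 11 false calls, and 0 calls when nothing was changed. A gene list shifted by -1 was recovered, with 0 of the other lists called. Probe sets were drawn independently of each other, so this does not check the list test where the genes of a list are correlated. Far fewer probe sets were changed there than the 6610 called in the data, which makes the adjusted threshold stricter. These shares therefore do not measure the recovery in this comparison, and a gene that did not pass may still have changed.

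Alternatives covered the signal filter, the normalization between arrays, the prior, array weights, a replicate block, leaving out each array, a fold threshold, the choice of probe set and the list test. Alternatives chosen after the data were seen were a covariate for the bioB hybridisation spike-in level, a covariate for the log2 ratio of 5' to 3' GAPDH, a floor of 4 and miR-200b replicate 3 alone against the controls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The control probe sets of 1 further transcript are not reported here.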

Results

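Messenger RNA levels were measured in HEY cells, an established human ovarian carcinoma line, 48 h after transfection with a precursor of miR-200b or with a negative control miRNA precursor. miR-200b is a microRNA best known for repressing ZEB1 and ZEB2, transcription factors that keep epithelial genes silent. The series belongs to a study of changes in the seed regions of human microRNAs, and its single comparison asks which transcripts differ between the 3 miR-200b samples and the 3 control samples. Each sample was read on 1 Affymetrix U133 Plus 2 array of 54675 probe sets, and the number of arrays limits the precision. The values are GCRMA signals on the log2 scale. Array medians lay between 1.37 and 1.48. Mature miRNA is not measured on these arrays, so the level of miR-200b itself was not checked. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

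HEY cells given miR-200b had lower ZEB1, ZEB2 and fibronectin (FN1), much lower chemokine transcripts led by CXCL8, lower MYC, and higher levels of a group of epithelial genes led by PKP3, ESRP1 and CDS1. Of 11842 genes tested with limma, 3009 changed at an adjusted p below 0.05, with 1684 higher and 1325 lower after miR-200b, and 2270 of them changed at least 2-fold. The majority turned with the log2 ratio of 5' to 3' GAPDH as a covariate (the GAPDH covariate), to 843 higher and 1274 lower, and with values below 4 raised to 4, to 777 higher and 866 lower. Of 27306 probe sets tested, 6610 changed, 2974 higher and 3636 lower, and without miR-200b replicate 3 the majority turned, to 4668 higher and 4018 lower. Among 23 gene lists that could be tested, the list of NF-kB and inflammatory cytokine genes and the list of reported targets of the miR-200b seed were lower as sets, and the epithelial junction and identity list was higher. With an estimated correlation 0 lists passed (adjusted p = 0.366, 0.451 and 0.451 in that order), and the epithelial list also missed the threshold with the GAPDH covariate (adjusted p = 0.179). The first principal component held 59.4% of the variance and separated the groups. Correlations between arrays of different groups ran from 0.910 to 0.946, against 0.981 to 0.987 within the controls and 0.943 to 0.985 within the miR-200b arrays.

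The 5' end of the GAPDH transcript, a common sign of cDNA coverage and RNA quality, differed between the groups. The 5' GAPDH control probe set read 12.05, 10.83 and 5.83 on the miR-200b arrays and 3.34, 2.55 and 4.31 on the control arrays, while the 3' GAPDH control probe set averaged 13.03 ± 0.06 and 12.64 ± 0.24 (SD, n = 3 each). The exact permutation test of either difference gave p = 0.1, two-sided, the smallest that 3 against 3 samples allow. The 5' ACTB control probe set averaged 4.0 ± 2.76 against 1.87 ± 0.19 (exact permutation p = 0.4), and miR-200b replicate 3, at 1.07, lay below all controls. The limma result with the GAPDH covariate is therefore given beside that without it, for each gene list fixed in advance and the largest falls and rises. This covariate was chosen after the data were seen. The log2 ratio was -0.94, -2.27 and -7.17 on the miR-200b arrays and -9.48, -9.81 and -8.43 on the controls. Within groups it varies mainly through miR-200b replicate 3. The covariate results therefore rest largely on that array and can lie beyond the values of any array.

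**Figure D1:**
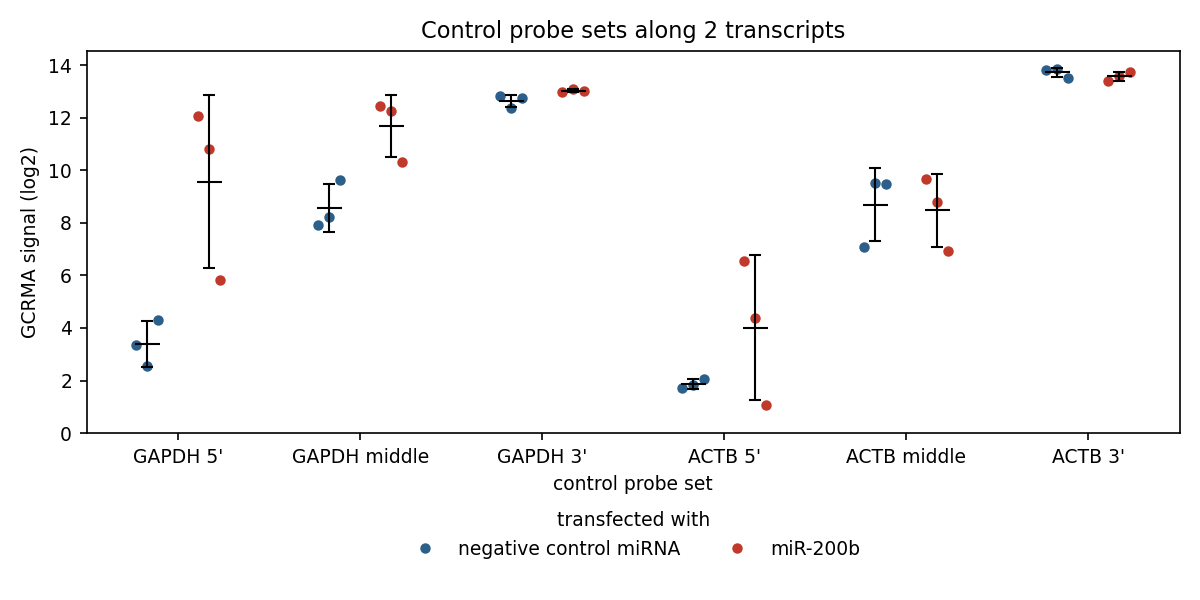
Control probe sets along the GAPDH and ACTB transcripts, with the GCRMA signal (log2) on the vertical axis, 1 point per array, and the mean ± SD of 3 arrays as bars. The 5' GAPDH points of the miR-200b arrays lie between 5.83 and 12.05 and those of the controls between 2.55 and 4.31, while the 3' GAPDH means are 13.03 and 12.64.

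Reported targets of miR-200b and of family members with the same seed were lower as a list fixed before the data were examined. Of 37 tested members, 11 fell, 5 rose and 21 did not pass, with a median log2 fold change of -0.68, which was -0.41 without miR-200b replicate 3. ZEB1 fell from 9.78 ± 0.20 to 7.10 ± 0.55 (SD, n = 3 each), a log2 fold change of -2.68 ± 0.31 (SE, limma adjusted p = 0.00394), and ZEB2 fell from 6.24 ± 0.22 to 4.01 ± 0.55 (-2.22 ± 0.31, limma adjusted p = 0.00610). FN1, the extracellular matrix glycoprotein fibronectin, fell 15.2-fold, from 11.47 ± 0.06 to 7.54 ± 0.89 (-3.93 ± 0.42, limma adjusted p = 0.00347), and 5 of its 6 other tested probe sets also fell. KLHL20, a substrate adaptor of a ubiquitin ligase, SEC23A, a coat protein of vesicles leaving the endoplasmic reticulum, and XIAP, an inhibitor of caspases, also fell, with log2 fold changes of -2.69, -2.31 and -2.21. QKI, an RNA-binding splicing regulator, had a log2 fold change of -0.97 ± 0.22 (limma adjusted p = 0.0238). Of its 8 other tested probe sets 6 fell, among them dimmer ones at -2.45, -2.32 and -2.24. CFL2, an actin-severing cofilin, fell by 0.95, and a dimmer probe set of it was at -1.61 (limma adjusted p = 0.00514). WASF3, a regulator of actin branching, was at -1.60 ± 0.58 (limma adjusted p = 0.0848), which did not pass. With the GAPDH covariate it was at -3.53 (limma adjusted p = 0.00852), which did, though miR-200b replicate 3 alone stood at -2.89 against the controls. The 5 reported targets that rose were PTPRD at 1.61, KEAP1 at 1.57, DNMT3A at 1.5, JAG1 at 1.24 and PLCG1 at 1.18. Adjusted over the list alone, 18 members passed, 13 lower and 5 higher. The list test (camera with a preset correlation) gave an adjusted p of 0.00520 over 23 lists, and adjusted p = 0.451 with an estimated correlation. The covariate gave a list median of -0.81 (adjusted p = 0.00862), with 13 members lower and 2 higher, and 9 of the 16 that had passed kept their call. ZEB1 then stood at -3.48, ZEB2 at -3.02 and FN1 at -2.45, all past the threshold, while QKI at -0.52 (adjusted p = 0.308) and CFL2 at -0.81 (adjusted p = 0.211) were not, nor were KEAP1, DNMT3A and JAG1. QKI and CFL2 also missed the threshold with median centring, each at a limma adjusted p of 0.0638. The covariate and centring values are those of each gene's brightest probe set. Without members that belong to several lists, FN1, ZEB1 and ZEB2 among them, the list had an adjusted p of 0.0870.

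**Figure D2:**
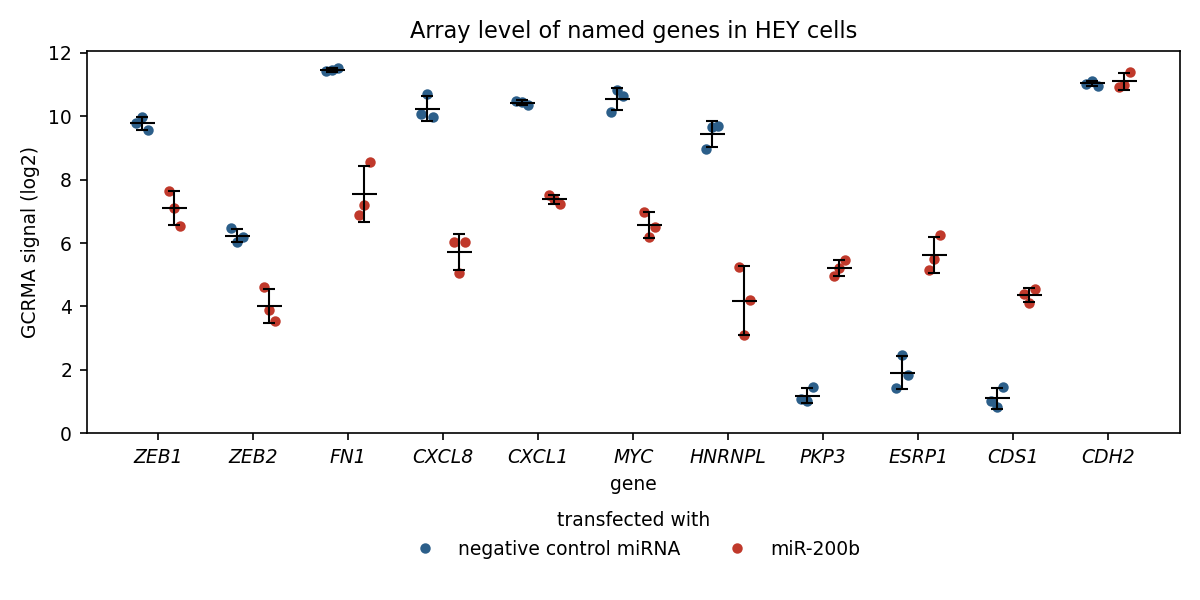
Array level of 11 genes, with the GCRMA signal (log2) on the vertical axis, 1 point per array, and the mean ± SD of 3 arrays per group as bars. ZEB1, ZEB2, FN1, CXCL8, CXCL1, MYC and HNRNPL are lower and PKP3, ESRP1 and CDS1 higher on all 3 miR-200b arrays than on all 3 control arrays, while CDH2 stands at 11.11 and 11.04.

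Epithelial junction and identity genes were higher as a list, with 8 of 17 tested members up, 0 down and 9 not past the threshold, and a median log2 fold change of 1.00. These 17 of 35 members on the array had passed the signal filter, and the median was 0.24 without the filter (adjusted p = 0.0269) and 0.27 with a filter at the 25th percentile (adjusted p = 0.0268). PKP3, a desmosome plaque protein, went from 1.18 ± 0.25 to 5.20 ± 0.25 (SD, n = 3 each; limma adjusted p = 0.00187), at least 8.90-fold higher. ESRP1, an epithelial splicing regulator, went from 1.91 ± 0.52 to 5.63 ± 0.56 (limma adjusted p = 0.00333), at least 11.9-fold higher, and CDS1, an enzyme of phospholipid synthesis, from 1.09 ± 0.32 to 4.36 ± 0.22 (limma adjusted p = 0.00233), at least 4.95-fold higher. These folds are lower bounds because the control level lay under 2.05, the highest value that 25 probe sets of blood and immune cell markers reached on any array. That level was chosen after the data were seen, and GCRMA background varies from probe to probe. The bounds hold only for a background at or under that level. With values below 4 raised to 4, the log2 fold changes of PKP3, ESRP1 and CDS1 were 1.20, 1.63 and 0.36. Dimmer tested probe sets of PKP3, ESRP1 and CDS1, at 0.24, 0.90 and 2.07 as fitted, did not pass, while another of CDS1 rose by 3.37. SPINT2, a membrane-bound protease inhibitor, was at least 2.62-fold higher, and the keratins KRT8, KRT7 and KRT18 rose by 2.32, 1.81 and 1.60 on the log2 scale. PATJ, a polarity scaffold at tight junctions, rose by 1.41. CDH1, encoding E-cadherin, stood at 0.93 ± 0.19 after miR-200b and 0.90 ± 0.26 in the controls, and EPCAM at 1.32 ± 0.12 and 0.80 ± 0.59 (SD, n = 3 each). Both lay below the signal filter and were not tested. Adjusted over the list alone, 8 members were higher and 1 lower. The list test gave an adjusted p of 0.0109, and adjusted p = 0.451 with an estimated correlation. The covariate brought the median to 0.74 and the list was no longer past the threshold (adjusted p = 0.179), with 5 members higher and 1 lower, though PKP3, ESRP1, CDS1 and SPINT2 stayed past it and the 3 keratins and PATJ did not. With values below 4 raised to 4, PKP3 and ESRP1 were the 2 members higher and the list had an adjusted p of 0.237. It also missed the threshold with a signal filter at the 75th percentile (adjusted p = 0.587) and with miR-200b replicate 3 alone against the controls (median 1.28, adjusted p = 0.117), where the spread comes from the control arrays only.

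Mesenchymal genes went both ways. Of 24 tested members 6 fell, 3 rose and 15 did not pass (median -0.23, camera adjusted p = 0.242). Beside FN1, ZEB1 and ZEB2, the collagen cross-linking enzyme LOX fell, at -3.49, as did the transcription factor SNAI2 at -1.58, and the collagen chain COL6A3 was at least 1.17-fold lower. LOXL2, another lysyl oxidase, rose by 1.38 and the microfibril protein FBN1 by 0.93, and the membrane protease MMP14 was at least 2.68-fold higher. The intermediate filament gene VIM, at -0.52 ± 0.33 (limma adjusted p = 0.289), did not pass, though its dimmer probe set fell by 1.67. With the GAPDH covariate the brighter one stood at -1.61 (limma adjusted p = 0.0181), and at -1.22 with miR-200b replicate 3 alone against the controls. CDH2, encoding N-cadherin, was at 0.07 ± 0.21 (limma adjusted p = 0.846). Adjusted over the list alone, 8 members were lower and 3 higher. With the covariate 6 members were lower and 3 higher, but in part other ones, as COL6A3, FBN1 and MMP14 lost their call and VIM, COL1A1 and S100A4 gained one.

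Among 26 extracellular matrix and integrin genes, 6 rose, 6 fell and 14 did not pass, and the count was the same adjusted over the list alone (camera adjusted p = 0.489). The matrix proteins TNC and THBS1 fell, at -1.78 and -2.65, and so did the metalloprotease inhibitor TIMP3 at -1.67, whereas the basement membrane chains COL4A2 and LAMA5 rose by 1.89 and 2.10 on the log2 scale. Of 38 actin cytoskeleton and motility genes, 4 rose, 1 fell and 33 did not pass (adjusted p = 0.650). The kinase LIMK1 rose by 1.5, the formin DIAPH1 by 1.47, the tropomyosin TPM2 by 1.69 and the small GTPase RHOC by 2.10, while CFL2 fell; adjusted over the list alone 5 passed. DIAPH1 had another probe set that fell. Of 24 genes of the TGF-beta pathway, 6 fell, 1 rose and 17 did not pass (adjusted p = 0.650). The receptors ACVR1, TGFBR2 and TGFBR3 fell, at -2.23, -1.70 and -1.0, and the latent TGF-beta binding protein LTBP1 rose by 1.45. Adjusted over the list alone, 6 were lower and 3 higher. Fitted with the GAPDH covariate, 3 matrix genes were higher and 5 lower, 0 actin genes were higher and 5 lower, and 1 TGF-beta gene was higher and 4 lower. Of the genes named, THBS1, LIMK1, DIAPH1, TPM2, RHOC, CFL2, TGFBR3 and LTBP1 lost their call, and the 5 actin genes that passed were other ones.

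NF-kB and inflammatory cytokine genes were lower as a list. Of 17 tested members 8 fell, 0 rose and 9 did not pass, and the median log2 fold change was -1.08. The median was -0.56 without miR-200b replicate 3 and -0.70 with the mean of a gene's probe sets, and the list stayed past the threshold in both. The neutrophil chemokine CXCL8 (interleukin 8) fell 23.3-fold, from 10.25 ± 0.40 to 5.71 ± 0.57 (SD, n = 3 each; log2 fold change -4.54 ± 0.35 SE, limma adjusted p = 0.00233); its other tested probe set did not pass. The related chemokines CXCL1, CXCL2 and CXCL3 fell 8.23-fold, 7.51-fold and 6.98-fold, with limma adjusted p of 0.00187, 0.00233 and 0.00275. The cytokine IL6, the chemokine CCL20, the NF-kB inhibitor NFKBIA and the cytokine IL1B fell as well, with log2 fold changes of -2.67, -1.87, -1.85 and -1.35. The 9 that did not pass were NFKB1 at -1.08, IL1A at -0.61, TNFAIP3 at -0.43, PTGS2 at 0.17, NFKB2 at 0.19, RELB at 0.27, LIF and TNF at 0.33 each and ICAM1 at 0.76. The count adjusted over the list alone was also 8. The list test gave an adjusted p of 8.87e-04, and adjusted p = 0.366 with an estimated correlation. With the GAPDH covariate the median was -1.78 (adjusted p = 5.80e-04) and 9 members were lower. Of the 8 that had fallen, 7 kept their call and IL1B did not (-0.91, adjusted p = 0.194), while NFKB1 gained one at -2.67 and ICAM1 turned to -2.38 (adjusted p = 0.0143). Without ICAM1 the median was -1.22, and -1.54 with the covariate.

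**Figure D3:**
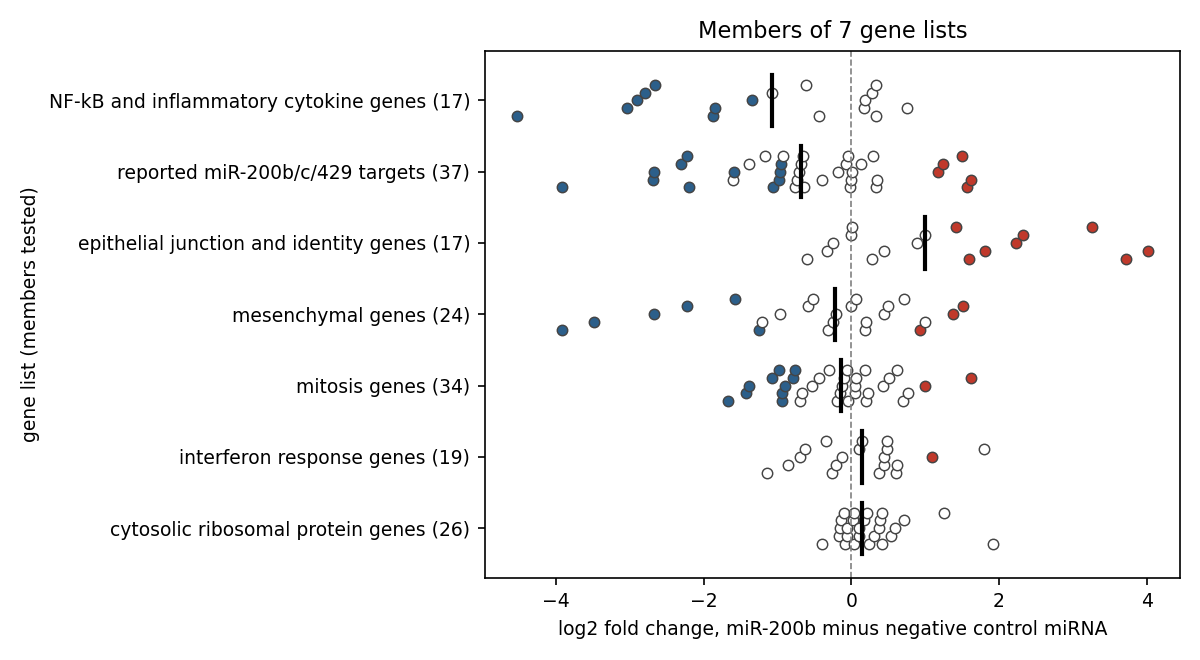
Log2 fold change, miR-200b minus negative control miRNA, of each tested member of 7 gene lists (1 point per gene, filled where the limma adjusted p is below 0.05, black bars at the medians), as fitted, also where a group lay near background. The 8 filled points of the NF-kB and inflammatory cytokine list lie between -4.54 and -1.35 and the 8 of the epithelial list between 1.41 and 4.02.

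Among all genes changed, HNRNPL, an RNA-binding splicing protein, fell most, 38.2-fold, from 9.44 ± 0.42 to 4.18 ± 1.08 (SD, n = 3 each; -5.25 ± 0.53 SE, limma adjusted p = 0.00333), and its second probe set fell by 4.46. The transcription factor MYC fell 15.7-fold, from 10.54 ± 0.36 to 6.57 ± 0.40 (limma adjusted p = 0.00233). The splicing factors SNRNP40 and PRPF39 fell, at -3.68 and -3.35, and so did the MDM2-binding protein MTBP at -3.88, the secreted semaphorin SEMA3C at -3.52 and the scavenger receptor COLEC12 at -3.38. MAMDC2, DNAAF2, TLNRD1 and the retinol dehydrogenase RDH10 complete the 14 largest falls after FN1, CXCL8 and LOX, at -3.66, -3.45, -3.44 and -3.32. Dimmer probe sets of SEMA3C at -2.28, LOX at -1.35 and MTBP at -1.13 also fell. Other tested probe sets of MTBP at -0.11, TLNRD1 at -0.38 and RDH10 at -0.73 and -0.11 did not pass. All 14 stayed past the threshold with the GAPDH covariate, and 11 did with values below 4 raised to 4, SNRNP40, DNAAF2 and RDH10 being lost. The largest rises were those of GIT1, a scaffold of ARF GTPase signalling, at 4.65 ± 0.66 (SE, limma adjusted p = 0.00641), and the proteasome ATPase PSMC3 at 4.51 ± 1.11 (limma adjusted p = 0.0282). The kinase co-chaperone CDC37 was at least 17.8-fold higher and ZBED2 at least 8.62-fold higher. ARPC4, a subunit of the actin-nucleating ARP2/3 complex, rose by 3.82, MORN4 by 3.74, SPECC1L by 3.73 and the transcription factor FOXH1 by 3.54. Other tested probe sets of ARPC4, at 1.69, and of MORN4, at -0.19, did not pass. CASKIN1 rose by 4.13, POLM, a DNA polymerase of end joining, by 3.68, UBE2S, a ubiquitin-conjugating enzyme of mitosis, was at least 10.2-fold higher and ZNF165 at least 5.66-fold. Of the 14 largest rises, 8 stayed past the threshold with the GAPDH covariate and 6 did not, namely GIT1, PSMC3, CASKIN1, POLM, UBE2S and ZNF165, and ZNF165 turned to a fitted -0.46. With values below 4 raised to 4, 7 of the 14 rises stayed past it, and PSMC3, CDC37, ZBED2, CASKIN1, POLM, UBE2S and ZNF165 did not. PSMC3 read 8.73, 8.36 and 5.02 on the miR-200b arrays and 1.33, 2.90 and 4.37 on the controls, and ZNF165 read 6.29, 5.28 and 2.07 and 0.54, 0.64 and 1.94, so that miR-200b replicate 3 added little to either rise. Of these 28 genes, 7 lost their call when some single array was left out, namely SNRNP40, RDH10, PSMC3, CASKIN1, UBE2S, FOXH1 and ZNF165. For 13 genes the fold itself, rather than its log2 value, moved by over 1.5 times. Without miR-200b replicate 3, SNRNP40, MTBP, MAMDC2, TLNRD1 and RDH10 stood at -2.72, -3.16, -2.94, -2.69 and -2.59, and GIT1, PSMC3, CDC37, CASKIN1, UBE2S and ZNF165 at 5.27, 5.68, 5.09, 4.90, 4.35 and 4.74. Without miR-200b replicate 1, SNRNP40, MTBP, MAMDC2 and RDH10 stood at -4.52, -4.58, -4.25 and -4.19, and PSMC3 and ZNF165 at 3.83 (adjusted p = 0.0619) and 2.63 (adjusted p = 0.0895). PSMC3 and CASKIN1 stood at 3.74 and 3.42 without control replicate 1 and at 5.26 and 4.73 without control replicate 3, POLM at 4.4 without control replicate 3 and FOXH1 at 2.86 without control replicate 2.

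Of 34 mitosis genes, 10 fell, 2 rose and 22 did not pass, with the same counts adjusted over the list alone; the list itself missed the threshold (median -0.15, camera adjusted p = 0.0870). The kinesins KIF23 and KIF20A fell, at -1.68 and -1.42, as did the cytokinesis protein ANLN at -1.38 and the ubiquitin-conjugating enzyme UBE2C at -1.07, while AURKB and KIF2C rose by 1.62 and 0.99. The list was past the threshold with the mean of a gene's probe sets (median -0.60, adjusted p = 0.00616), without the signal filter (adjusted p = 0.0262) and with a filter at the 25th percentile (adjusted p = 0.0345). Of 32 S-phase and DNA replication genes, 7 fell, 4 rose and 21 did not pass, and 10 were lower and 6 higher adjusted over the list alone. The list had a median of 0.12 and a mean of 0.01, though camera's direction was down (adjusted p = 0.709). The replication clamp PCNA fell, at -1.27, as did the thymidylate synthase TYMS at -1.04, while the helicase subunit MCM2 rose by 1.58 and the ribonucleotide reductase subunit RRM2 by 0.90. Other tested probe sets of TYMS, at 0.46 and 0.53, and of RRM2, at 0.12, did not pass. Fitted with the GAPDH covariate, 6 mitosis genes were lower and 0 higher, and 5 S-phase genes were lower and 1 higher. UBE2C, AURKB, KIF2C and MCM2 were among those that lost their call.

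Among 22 p53 response genes, 5 rose, 5 fell and 12 did not pass (median 0.48, adjusted p = 0.820; 7 higher and 5 lower adjusted over the list alone). The cell cycle inhibitor CDKN1A rose by 1.43 and the DNA damage sensor DDB2 by 1.34, while the ribonucleotide reductase subunit RRM2B and the stress-response gene SESN1 fell, at -1.19 and -1.27. Of 23 ER stress and integrated stress response genes, 5 rose, 4 fell and 14 did not pass (median 0.15, adjusted p = 0.709; 8 higher and 4 lower adjusted over the list alone). DDIT4, an inhibitor of mTORC1 signalling, rose 6.0-fold (2.58 ± 0.23 SE, limma adjusted p = 0.00275) and the asparagine synthetase ASNS by 1.25, while the transcription factor CEBPB fell by 1.87. The disulfide isomerase PDIA4 rose by 2.02, but another of its probe sets fell. Under the covariate 2 p53 response genes were higher and 4 lower, and 5 stress genes were higher and 1 lower, with CDKN1A, DDB2 and PDIA4 among those that lost their call. Of 19 interferon response genes, 1 rose and 18 did not pass, and 0 passed adjusted over the list alone (median 0.15, adjusted p = 0.955); 1 other gene, IFIT3, was higher with the covariate. The gene that rose was OAS3, a sensor of double-stranded RNA, at 1.09 ± 0.32 (limma adjusted p = 0.0456), which stood at 0.22 with the GAPDH covariate.

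Calls among markers of other cell types and control genes are to be read against the 25.4% of all tested genes that were called. Most of these lists are too short to tell their share from that one. All 12 blood and immune cell markers on the array lay below the filter. Of 5 tested fibroblast markers, 0 passed (median 0.19, mean -0.35, camera direction down, adjusted p = 0.820), and the same was true of 6 endothelial markers (median 0.12, adjusted p = 0.955). Adjusted over the list alone, 0 passed in either list. Under the covariate 2 fibroblast markers were higher and 1 lower, and 1 endothelial marker was higher. Of 8 ovarian carcinoma and Mullerian lineage genes, the folate receptor FOLR1 fell by 2.34, LY6E was at least 2.33-fold higher and 6 did not pass (median -0.13, adjusted p = 0.709). The count was 2 adjusted over the list alone, and with the covariate 1 was lower, 0 higher and LY6E stood at -0.02. Of 12 housekeeping genes, GUSB rose by 0.93 and GAPDH by 1.15 (limma adjusted p = 0.0499), and 10 did not pass. Adjusted over the list alone, 3 were higher and 1 lower. The list had a median of -0.19, a mean of 0.02 and a camera direction of down (adjusted p = 0.709). GAPDH stayed above 0 with quantile normalization, median centring and cyclic loess, at 1.24, 1.17 and 1.29, and stood at 0.16 with the GAPDH covariate, where 0 housekeeping genes passed. That covariate is read from GAPDH itself, so it is no independent check of this gene. Other tested probe sets of GAPDH, at 1.08 and 1.23, missed the threshold without it (limma adjusted p = 0.0521 and 0.0551). ACTB was at -0.14 ± 0.20 (limma adjusted p = 0.642), and at 0.02 with cyclic loess. Of 26 cytosolic ribosomal protein genes 0 passed, over all genes, adjusted over the list alone or with the covariate (median 0.14, adjusted p = 0.709).

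The number of changed probe sets depended on single arrays, at 2124 without miR-200b replicate 2 and at 2803, 2468 and 3204 without control replicates 1, 2 and 3. Of 1623 changed genes with a second tested probe set, that probe set had the same sign for 1278, was called the same way for 530 and the opposite way for 56.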

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

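The tests with the 5' to 3' GAPDH ratio or the bioB spike-in level, and the counts of other splits for probe sets and genes, were chosen after the results they bear on were seen. Control probe sets outside the main comparison carried a signal above that of the control samples: the 5' GAPDH control probe set was 6.17 higher and the middle GAPDH control probe set 3.10 higher on the log2 scale after miR-200b (exact permutation p = 0.1 each, the smallest that 3 against 3 arrays allow).

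The pattern weighed first is the 6610 changed probe sets, with 5' coverage of the cDNA as the technical explanation and the miR-200b treatment as the biological one. With the 5' to 3' GAPDH ratio as a covariate, 2866 of them kept call and direction and 0 were called the opposite way. The NF-kB and inflammatory cytokine list (median -1.08 without and -1.78 with the covariate, camera adjusted p = 5.80e-04) and the reported targets (-0.68 and -0.81, camera adjusted p = 0.00862) stayed lower. This argues against a linear trend in this ratio as the whole cause for these. It does not exclude coverage itself, because a ratio that reads coverage imperfectly can leave coverage effects in the group term. The other 3744 lost their call; their median size went from 1.16 to 0.905, or 78.0% of its value, while the median SE went from 0.26 to 0.40, so the calls ended through both, and for these probe sets, 2115 of them higher, coverage and treatment cannot be told apart. The same holds for the epithelial list, whose median went from 1.00 to 0.74 (adjusted p = 0.179). What keeps it open is that the ratio is read from 1 transcript and correlates with the group at r = 0.830. Within groups the ratio varies mainly through miR-200b replicate 3. The covariate median of the NF-kB list, -1.78, also lies beyond the -1.10 of that array alone and the -0.56 without it.

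The pattern weighed next is the spread along the second principal component, which held 25.8% of the variance. The bioB hybridisation spike-in level, which would fall with more target relative to the spike, correlated with this component across the 6 arrays at Pearson r = -0.946 (exact permutation p = 0.00833, adjusted p = 0.025 over 3 relations; Spearman rho = -0.829, exact permutation p = 0.0583), at r = -0.766 without the 2 arrays farthest from its median, at -0.996 within the miR-200b arrays and at -0.679 within the controls. The 5' to 3' GAPDH ratio, with both centred within groups, correlated with it at Pearson r = 0.961 (exact permutation p within groups = 0.111, adjusted p = 0.167; Spearman rho = 0.829, exact permutation p = 0.222), at r = 0.566 without the 2 farthest arrays, at 0.999 within the miR-200b arrays and at 0.196 within the controls. Centred within groups like the ratio, the bioB level correlated with the component at r = -0.948 (exact permutation p within groups = 0.0556). Tested alike, neither measure had a p under 0.05. The amount of labelled target and 5' coverage are therefore both candidate explanations, and these tests do not rank them. A treatment effect of varying strength stays open as well. All 3 controls lay inside the range of the miR-200b arrays. A first component that separates the groups, however, leaves the second little room to separate them too. The spike-in level correlated with the first component at 0.107, and with it as a covariate all 6610 changed probe sets stayed changed in the same direction.

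In limma, 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave as many changed probe sets, changed genes or called gene lists as were found. The real values were 6610, 3009 and 3, and the highest of the other splits 0, 0 and 2; 10 splits are too few for a share under 0.05.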

How the results depend on the processing

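Results under the spike-in covariate, the GAPDH covariate, the floor of 4 and miR-200b replicate 3 alone against the controls were chosen after the data were seen. The number of changed probe sets, 6610, was 4875 to 7069 under other signal filters, normalizations, priors and array weights, 1799 when tested against a log2 fold change of 0.5, 3072 with the floor of 4 (the floor removes differences among dim probe sets), 9958 with the spike-in covariate, where the cause was not tested, 6315 with miR-200b replicate 3 alone (spread from the controls only) and 5471 with the GAPDH covariate, of which 27.7% were higher against 45.0% without it. The number of changed genes, 3009, was 1643 with the floor. Leaving out each array in turn gave 2124 to 8686 probe sets and 863 to 3807 genes, with fewer samples in each fit. The arrays that moved the counts by over 1.5 times were miR-200b replicate 2 (2124 and 863) and control replicates 1 (2803 and 1197), 2 (2468 and 1015) and 3 (3204 and 1450). With a replicate block, 2714 probe sets and 1126 genes changed. The deviations of same-numbered arrays correlated at -0.339, -0.0827 and -0.0958, which gives no sign of pairing but cannot exclude it. The control titles say that they were analyzed with miR200b and hold a replicate number, and pairing is not stated. Of the gene list tests, 3 were past the threshold, 0 with an estimated correlation and 2 to 4 in all other settings. Over all settings, the called lists kept direction and call in 61 values and lost the call in 8, and the named genes that changed did so in 1483 values, lost it in 313 and turned direction in 2: ZNF165 at -0.46 and LY6E at -0.023 with the GAPDH covariate, where the cause was not tested. Between 27.3% and 29.7% of probe sets per array lay above 4, so differences among the rest are measured near background. Tests of genes with seed sites, and the settings meant for them, were not run, because 3' UTR sequence was not used here. Genes whose values all lie at the floor have no value under it.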

Other observations

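The test of secreted factors and the genes named outside the fixed lists were chosen after values were seen. Some regulators of chromatin, Notch signalling and small-RNA silencing changed after miR-200b, as did 25.4% of all genes tested. None of these lists passed the list test. Of 22 polycomb, DNA methylation and chromatin repressor genes, 4 rose, 4 fell and 14 did not pass (limma, also 4 and 4 adjusted over the list alone). The histone deacetylase HDAC1 rose by 1.12 while its paralog HDAC2 fell, at -1.0, and the DNA demethylases TET2 and TET3 fell, at -1.10 and -2.08, while the DNA methyltransferase DNMT3A rose by 1.5, with another of its probe sets lower. The list's median was 0.04, with camera's direction down (adjusted p = 0.834). Of 18 Notch pathway genes, 2 rose, 3 fell and 13 did not pass, with the same counts adjusted over the list alone (median -0.11, adjusted p = 0.709). The ligand JAG1 and the glycosyltransferase LFNG rose by 1.24 and 1.06, and the coactivator MAML2 fell, at -2.42. Of 24 genes of the small-RNA silencing machinery, 4 fell, 0 rose and 20 did not pass, and 2 were lower adjusted over the list alone (median -0.16, adjusted p = 0.361). The deadenylase subunit CNOT8, the Dicer partner PRKRA and the decapping factor DCP1A fell, at -0.97, -0.94 and -0.78. Other tested probe sets of CNOT8, at 0.20 and -1.61, and of DCP1A, at 0.27, did not pass. Fitted with the GAPDH covariate, 2 chromatin genes were higher and 5 lower, 2 Notch genes higher and 3 lower, and 1 silencing gene higher and 5 lower. These were in part other genes, since HDAC1, HDAC2, DNMT3A, JAG1, NUMB, NOTCH2 and DCP1A lost their call and HEY1, RBPJ and NOTCH1 gained one.

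No metabolic list passed the list test. Of 15 cholesterol synthesis genes, the epoxidase SQLE, INSIG1 and STARD4 fell, at -1.63, -1.26 and -1.33, FDPS and LSS rose by 0.85 and 1.02, and 10 did not pass (median 0.24, adjusted p = 0.834; 5 higher and 3 lower adjusted over the list alone). Of 21 hypoxia and glycolysis genes, the glucose transporter SLC2A1, PFKP and ENO2 rose by 1.05, 0.96 and 0.96, P4HA1 fell, at -1.31, and 17 did not pass (median 0.26, adjusted p = 0.709; 3 higher and 1 lower adjusted over the list alone). Of 30 oxidative phosphorylation genes, UQCRC1, NDUFS3 and NDUFA2 rose by 2.24, 0.80 and 0.74, SDHD fell, at -0.68, and 26 did not pass (median 0.12, adjusted p = 0.709; 1 higher adjusted over the list alone). Under the GAPDH covariate 1 cholesterol gene was higher and 1 lower, 0 glycolysis genes passed and 1 oxidative phosphorylation gene was higher.

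Genes named after their values were seen include the chromatin architecture gene HMGA2, which fell by 1.89 (limma adjusted p = 0.00377), the phosphatase DUSP1, which fell by 1.80, the kinase CDK6, which fell by 0.90, and the cyclin CCND1, which rose by 1.15. Their values with the GAPDH covariate are not given here.

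MYC fell by 3.98, which led to the hypothesis that genes MYC is known to activate are lower as a set. Of 27 tested genes of such a list, 2 fell, 3 rose and 22 did not pass, with a median log2 fold change of 0.057 and a 95% interval of -0.21 to 0.52 from the order of the members (limma camera adjusted p = 0.880 over 2 added lists). ODC1 and UTP20 fell, at -1.29 and -1.39, while SLC19A1, CAD and MRTO4 rose by 2.49, 1.26 and 0.88. No shift was found. The interval is taken over genes that went both ways on the same arrays and holds no error between arrays, so it does not exclude one. With the GAPDH covariate the camera adjusted p was 0.929.

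The falls of CXCL8, CXCL1 and IL6 led to the hypothesis that other secreted growth factors and cytokines are lower as well. Of 21 tested genes outside the NF-kB list, 3 fell, 5 rose and 13 did not pass, with a median of 0.40 and a 95% interval of -0.49 to 1.00 (limma camera adjusted p = 0.880). The interleukins IL7 and IL15 fell, at -2.86 and -1.45, and the growth factor CSF1 was at least 1.9-fold lower, while IL18, NRG1, HBEGF and GDF11 rose by 1.27, 1.27, 1.45 and 1.71 and IL11 was at least 1.52-fold higher. The interval is too wide to exclude a fall of the set, and it too holds no error between arrays. The camera adjusted p with the GAPDH covariate was 0.929. A search over 142 families of genes that share a symbol prefix, each of at least 10 tested genes, called 0 families with limma's camera, and 10 had an unadjusted p below 0.05.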
